A study of Mus musculus with 26 samples.

How the data were processed

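RNA sequencing libraries of GFP-positive cells from early mouse gliomas were analysed, 26 in all. Per the labels' protocols, GFP marked cells in which Cre had acted on a reporter at the Rosa locus, tumours were dissected, GFP-positive cells were sorted by flow cytometry, RNA was taken up in TRIzol, libraries were made with the TruSeq Stranded RNA LT kit and sequencing was done on an Illumina NextSeq instrument. The deposited table holds counts per gene, with Entrez gene identifiers and a gene length that no test used. Reads were aligned with STAR to mm10, per the submitters' processing notes. The version of STAR, the tool that counted reads, its annotation and its strand setting are not given in the sources used here, so counts of overlapping and antisense genes and of genes with near-identical copies are uncertain. Values were whole numbers whose totals differed between libraries, and no further normalization was found in them.

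Each library was put in its genotype by its label. Replicate numbers come from the titles. Symbols and positions come from a RefSeq gene table of assembly GRCm38.p6, the assembly called mm10. Of 24454 genes listed, 24374 matched by Entrez identifier, and the other 80, with 0.348% of all counts, kept their identifier as name.

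Genes were filtered with filterByExpr by genotype, which left 15617, and scaled by TMM. All 26 libraries entered 1 fit with genotype as the only term, so that genotypes shared an estimate of the spread per gene. Each contrast was tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, and p-values were adjusted over genes by Benjamini-Hochberg with a threshold of 0.05. A gene is said to have risen, fallen or changed where it passed, and standard errors were taken from the log2 fold change and its F statistic. The common biological coefficient of variation was 0.368. CPM values, counts scaled to a common library total, used TMM-scaled totals, and log2 CPM a prior count of 2. The contrasts were each of Rbpj-/-, Notch1-/-Notch2-/-, Notch1-/- and Notch2-/- against control, Rbpj-/- against Notch1-/-Notch2-/-, Notch1-/- against Notch2-/-, and the interaction of both losses.

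Of 33 gene lists, 32 had at least 3 genes tested. They covered Notch target genes, Notch pathway components, the astrocyte, neural stem and progenitor, oligodendrocyte precursor, mature oligodendrocyte, proneural and early neuronal, mature neuron, microglia and macrophage, infiltrating myeloid, T and NK cell, B cell, endothelial, mural and fibroblast, ependymal and erythroid cell types, MHC class I and II antigen presentation, the responses to interferon gamma and type I interferon, interferon receptors, cytokines and chemokines, cell cycle, p53 targets, MAPK output, immediate early and dissociation stress, hypoxia, mesenchymal glioma, BMP and Id genes, Wnt targets, YAP and TEAD targets and cholesterol biosynthesis. Mitochondrially encoded genes matched no gene of the table and were not analysed here. Lists were tested with camera of limma 3.58.1 on voom values at a preset correlation between genes of 0.01, adjusted over the lists, and again with a correlation estimated from the data. The score of a list is its mean log2 CPM, compared between genotypes by an exact two-sided permutation test and adjusted over the lists of other cell types.

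Genes were named by a rule: Notch1, Notch2, Rbpj and Trp53 in every contrast; the 10 largest rises and falls per contrast with a mean log2 CPM of at least 1 and every library of the first group, save at most 1, on the same side of the median of the second; and up to 4 members per list with the smallest adjusted p, or the 2 most expressed where none passed. Predicted genes, pseudogenes, Xist, Tsix and Y-linked genes were left out of the largest changes, and the side was not asked of the interaction. Among the genes this rule gives, those described were picked after their values were seen, with preference for calls that held without each library and under the covariates, while counts of calls that held cover every gene it gives. Single results of a few genes that the rule gives are not reported here. Contrasts, tests, lists, this rule and most alternatives were fixed before the data were examined, and the closing section names those that were not.

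Alternatives, tried singly, were size factors of DESeq2, no filter, a filter of 10 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, limma voom with quality weights, the replicate number as a block, only the compared libraries in the fit, the microglia and macrophage score or the log2 CPM of Xist as a covariate, and each library left out in turn. Lists were also tested with fry, which asks only whether the genes of a list move one way on balance. The overlap of contrasts that share the controls was set beside unchanged groups simulated against those controls and beside controls split 3 and 3 between the contrasts. The procedure was tested on simulated counts with known changes.

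In that test, on 15480 genes, changes of 1 on the log2 scale were found at 44.0% of 100 genes for Rbpj-/- against control, and changes of 2 at 86.9% of 99. For Notch2-/- against control, on 15482 genes, the shares were 57.6% and 79.8%. Total counts of 30868828 to 48103535 per library put the error of an expressed gene mostly in the spread between libraries rather than in counting.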

Results

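RNA was sequenced from GFP-positive cells sorted out of early gliomas of mice. The tumours were driven by PDGF in the absence of the tumour suppressor Trp53, and GFP came from a reporter that Cre recombinase switches on. The tumours of 5 genotypes were compared: tumours with intact Notch signalling (control, n = 6), and tumours labelled Notch1-/- (n = 6), Notch2-/- (n = 5), Notch1-/-Notch2-/- (n = 5) and Rbpj-/- (n = 4). Notch1 and Notch2 are receptors that are cleaved on contact with a ligand of a neighbouring cell, and Rbpj is the DNA-binding protein through which their released intracellular parts switch genes on. Total counts per library were 37613009 to 46703709 in the control group, 31593287 to 42378306 in Notch1-/-, 37786708 to 48103535 in Notch2-/-, 35046873 to 44376594 in Notch1-/-Notch2-/- and 30868828 to 44302365 in Rbpj-/-. 15617 genes had enough counts to be tested. The labels do not say that replicates of a genotype came from separate animals, so p-values measure only the spread between these samples, which may be technical. Within genotypes the 56 pairs of libraries differed by more than sampling noise (lowest chi-square per gene 45.0), with correlations of log2 CPM across genes of 0.900 to 0.984. The first 3 principal components held 30.0%, 19.5% and 11.8% of the variance. The sex of the animals was not in the labels. Control replicate 1, Notch1-/-Notch2-/- replicates 1 and 2 and Rbpj-/- replicate 2 had Xist, the RNA that silences an X chromosome in females, at 1624, 3428, 3463 and 3465 CPM and the Y-linked gene Ddx3y at 0 CPM. Control replicate 6 and Notch2-/- replicates 3 and 4 had both, and are called mixed below, with Xist at 412, 71.3 and 1918 CPM and Ddx3y at 64.0, 45.9 and 74.1 CPM. In the other libraries Ddx3y was present and Xist was at or below 4.81 CPM. Below, list-wise counts are of genes that pass when adjusted over their list alone, a camera p followed by an estimated one is given again with the correlation between genes estimated from the data, ± is the standard error of a log2 fold change or the standard deviation of a level in CPM, and adjusted p for a gene is that of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

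The deleted genes were read first in every library. Notch2 (Entrez gene 18129, chromosome 3, 98013538 to 98150367 in GRCm38.p6) had 6.14, 8.58, 7.34, 7.90 and 6.79 CPM in Notch2-/- replicates 1 to 5, below every control library (9.42 to 16.4 CPM). Its level was 7.35 ± 0.950 CPM in Notch2-/- against 12.7 ± 2.73 CPM in control (log2 fold change -0.79 ± 0.15, adjusted p = 0.0200), a call that ended without Notch2-/- replicates 1 (0.0790) and 5 (0.0717) and control replicate 5 (0.0564). In Notch1-/-Notch2-/- replicates 1 to 5 Notch2 had 11.4, 11.8, 12.9, 10.5 and 9.43 CPM, above every Notch2-/- library and not called below control (-0.18 ± 0.15, adjusted p = 0.377). Rbpj (Entrez gene 19664, chromosome 5, 53555779 to 53657445) had 20.4, 35.0, 43.7 and 52.0 CPM in Rbpj-/- replicates 1 to 4, against 52.9 to 68.0 CPM in the controls. It fell in Rbpj-/- (-0.70 ± 0.20, adjusted p = 0.0222), a call that ended without Rbpj-/- replicates 1 (0.0735) and 2 (0.0664). Notch1 (Entrez gene 18128, chromosome 2, 26457902 to 26503822) was not lower in the libraries labelled Notch1-/-, where replicates 1 to 6 had 105, 172, 141, 143, 88.2 and 214 CPM against 71.2 to 148 CPM in the controls (0.40 ± 0.24, adjusted p = 0.204). In Notch1-/-Notch2-/- replicates 1 to 5 it had 111, 139, 124, 239 and 82.7 CPM (0.36 ± 0.25, adjusted p = 0.270). Whole-gene counts need not show an exon deletion, and the labels do not say which part was deleted. Notch1 levels thus neither bear out nor contradict them. Notch2 did not bear out the label Notch1-/-Notch2-/-. Genotype names here mean the labels. Notch1 was higher in Rbpj-/-, at 195 ± 59.0 CPM against 109 ± 30.8 CPM (0.84 ± 0.26, adjusted p = 0.0340), a call that ended without control replicates 1 (0.0577), 2 (0.0823), 3 (0.0642) and 6 (0.0674) and Rbpj-/- replicates 1 (0.0687), 2 (0.132) and 4 (0.0738). Trp53 (Entrez gene 22059, chromosome 11, 69580348 to 69591873), deleted in every group, had 10.8 ± 2.27 CPM in control, 12.7 ± 1.67 in Notch1-/-, 10.9 ± 2.65 in Notch2-/-, 14.0 ± 0.721 in Notch1-/-Notch2-/- and 13.6 ± 3.07 in Rbpj-/-, with no group of intact Trp53 to compare with.

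**Figure D1:**
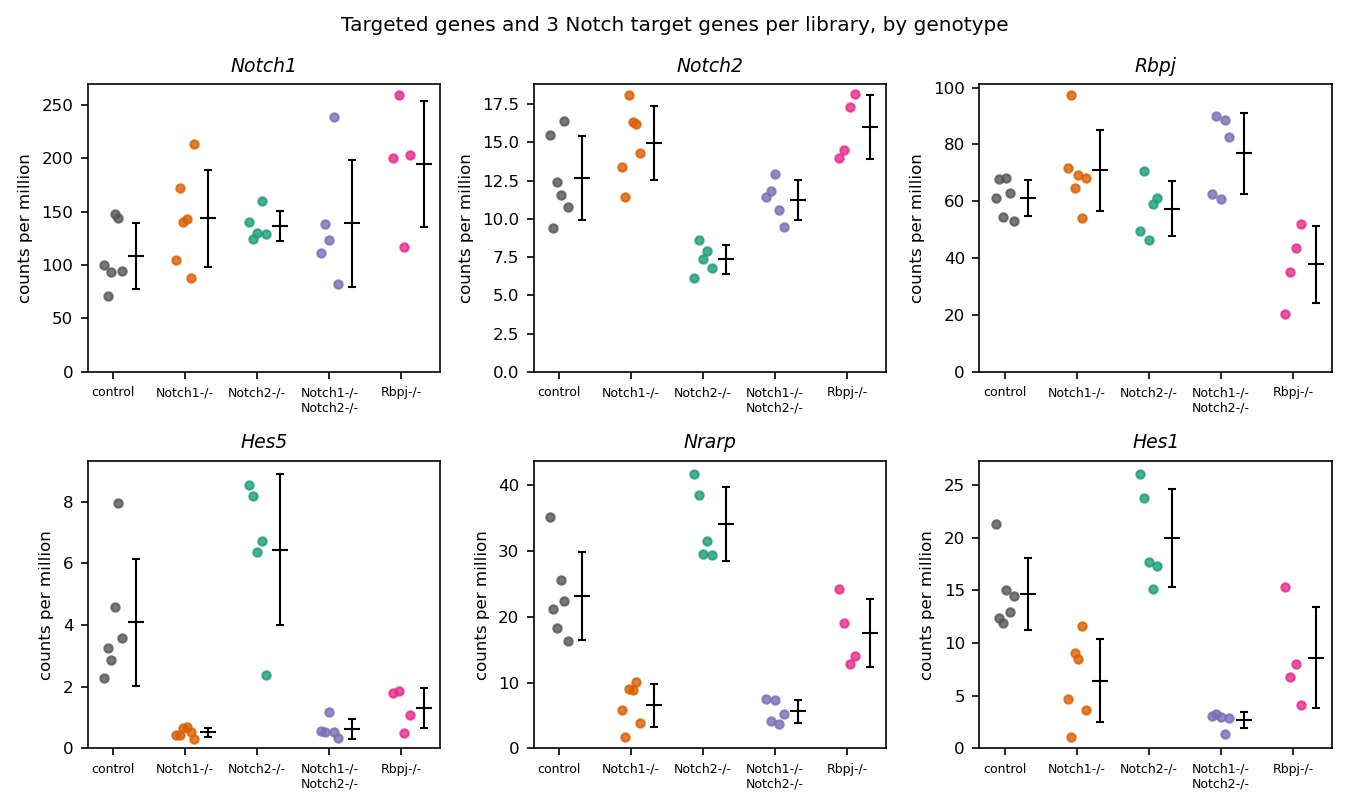
CPM (y axis) of the targeted genes Notch1, Notch2 and Rbpj and of the Notch target genes Hes5, Nrarp and Hes1 in the 26 libraries (points), by genotype (x axis), with the mean and standard deviation in black. Notch2 lies at 6.14 to 8.58 CPM in Notch2-/- against 9.42 to 16.4 CPM in control, and Hes5 at 0.312 to 0.705 CPM in Notch1-/- and 0.333 to 1.19 CPM in Notch1-/-Notch2-/- against 2.27 to 7.97 CPM in control.

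The first comparison asked what changes when the DNA-binding effector shared by Notch receptors is lost. Hes5 (Entrez gene 15208, chromosome 4, 154960626 to 154962372), a repressor of neuronal differentiation that Notch switches on, fell to 1.31 ± 0.654 CPM (n = 4) from 4.09 ± 2.05 CPM (n = 6). Many astrocyte, microglia, endothelial and mature oligodendrocyte genes fell, and 9 cell cycle genes rose. The axon guidance receptor Unc5d rose from 3.01 ± 1.65 to 24.7 ± 10.4 CPM. Of 15617 genes tested with edgeR, 1245 rose and 1133 fell. Of these, 80 of the 84 given by the naming rule were on the same side of the control median in 4 of 4 libraries.

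Among Notch genes, 1 of 10 targets fell (1 list-wise, camera adjusted p = 0.20). It was Hes5 (log2 fold change -1.64 ± 0.43, adjusted p = 0.0148). 3 of 22 pathway components rose and 2 fell (the same counts list-wise, camera adjusted p = 0.615). The ligand Dll3 (0.63 ± 0.16) rose, with adjusted p = 0.0133. In astrocytes' genes, 8 of 20 members fell (10 fell list-wise, camera adjusted p = 1.99e-07, or 0.0492 estimated). The bicarbonate transporter Slc4a4 (-2.42 ± 0.36), the water channel Aqp4 (-2.69 ± 0.49), the membrane protein Mlc1 (-2.46 ± 0.44) and glutamine synthetase Glul (-0.90 ± 0.18) fell, with adjusted p of 4.83e-04 to 0.00408. The stem cell surface protein Prom1 (-2.40 ± 0.50), the bHLH inhibitor Id4 (-2.17 ± 0.37) and the growth factor Bmp2 (-1.54 ± 0.35) also fell, with adjusted p of 0.00135 to 0.00767. In the cell cycle list, 9 of 30 genes rose (14 rose list-wise, camera adjusted p = 3.20e-07, or 0.632 estimated). Among them were the spindle checkpoint kinase Bub1b (1.12 ± 0.26, adjusted p = 0.00898) and the mitotic transcription factor Foxm1 (1.11 ± 0.27, adjusted p = 0.0115). In cholesterol biosynthesis, 3 of 19 genes fell (3 list-wise, camera adjusted p = 6.69e-04, or 0.632 estimated). Msmo1 stood at -0.89 ± 0.22 (adjusted p = 0.0114).

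Among the largest changes, Unc5d (3.04 ± 0.53) and the secreted neuron guide Reln (3.00 ± 0.72) rose, with adjusted p of 0.00187 to 0.010, and so did the imprinted gene Dlk1 (3.43 ± 0.85, adjusted p = 0.0121), a call that ended without Rbpj-/- replicate 1 (0.0842), and the hyaluronan receptor Cd44 (3.32 ± 0.91, adjusted p = 0.0186), a call that ended without Rbpj-/- replicate 1 (0.0805). Trnp1, a nuclear protein of neural progenitors, fell from 38.9 ± 7.23 to 2.59 ± 1.28 CPM (-3.91 ± 0.45, adjusted p = 1.83e-05).

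Markers of other cell types moved with these groups. Of microglia and macrophages, 18 of 21 genes fell (20 fell list-wise, camera adjusted p = 1.95e-17, or 0.291 estimated): the purinergic receptor P2ry12 fell from 44.3 ± 22.6 to 5.4 ± 3.01 CPM, and P2ry12 (-3.04 ± 0.50), Siglech (-3.11 ± 0.49) and Ctss (-3.32 ± 0.72) all fell, with adjusted p of 8.13e-04 to 0.00593. Of the endothelium, 8 of 15 genes fell (8 list-wise, camera adjusted p = 5.06e-07, or 0.381 estimated). The angiopoietin receptor Tek (-2.85 ± 0.55) and the blood-brain barrier transporter Slco1a4 (-3.63 ± 0.72) fell, with adjusted p of 0.00320 to 0.00377. Of mural cells and fibroblasts, 2 of 14 genes fell (2 list-wise, camera adjusted p = 0.00751, or 0.632 estimated). The pericyte genes Vtn (-3.08 ± 0.60) and Rgs5 (-2.65 ± 0.57) fell, with adjusted p of 0.00340 to 0.00593. Of mature oligodendrocytes, 9 of 16 genes fell (11 fell list-wise, camera adjusted p = 4.77e-08, or 0.519 estimated). The myelin glycoprotein Mog (-3.08 ± 0.73) and the aspartoacylase Aspa (-2.96 ± 0.74) fell, with adjusted p of 0.00938 to 0.0125. Of infiltrating myeloid cells, 2 of 10 genes fell (2 list-wise, camera adjusted p = 0.0373, or 0.632 estimated). Of erythroid cells, 0 of 7 genes passed with edgeR, 0 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with voom (0 list-wise, camera adjusted p = 0.0373, or 0.671 estimated). Of B cells, 2 of 3 genes fell (1 rose and 2 fell list-wise, camera adjusted p = 0.377). Mural and fibroblast lost its call without Rbpj-/- replicate 2 (0.135). Infiltrating myeloid lost its call without Rbpj-/- replicates 1 (0.0676), 2 (0.127) and 3 (0.0700) and control replicate 5 (0.0530). Erythroid lost its call without control replicates 1 (0.0508) and 3 (0.0565) and Rbpj-/- replicate 3 (0.183).

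Lists of antigen presentation and interferon response were lower by camera with few members past the threshold. 0 of 22 MHC class I genes passed with edgeR, 4 at an unadjusted p under 0.05, 2 with DESeq2 and 0 with voom (0 list-wise, camera adjusted p = 0.00267, or 0.671 estimated). 2 of 10 MHC class II genes fell (2 list-wise, camera adjusted p = 0.00185, or 0.632 estimated). 1 of 29 interferon gamma response genes fell (0 list-wise, camera adjusted p = 6.69e-04, or 0.671 estimated). 0 of 26 type I interferon response genes passed with edgeR, 8 at an unadjusted p under 0.05, 4 with DESeq2 and 0 with voom (0 list-wise, camera adjusted p = 4.80e-04, or 0.671 estimated). 6 of 23 cytokines and chemokines fell (7 fell list-wise, camera adjusted p = 0.00881, or 0.561 estimated). With the microglia and macrophage score as a covariate camera's direction turned, at mean log2 fold changes (camera adjusted p) of 1.06 (0.197) for MHC class I, 1.64 (0.386) for MHC class II, 1.28 (0.0991) for interferon gamma, 0.72 (0.257) for type I interferon and 1.12 (0.425) for infiltrating myeloid cells.

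As mean log2 CPM of a list, the Rbpj-/- libraries differed from control by -2.37 for microglia and macrophage, -1.71 for endothelial, -1.28 for mural and fibroblast, -1.95 for mature oligodendrocyte and -1.03 for erythroid (p = 0.00476 to 0.0143, adjusted p = 0.0214 to 0.0257, exact two-sided permutation over 210 splits). The microglia and macrophage score had 78.9% of its variance between the 5 genotypes. Added as a covariate, the microglia and macrophage score left 42 (17 up, 25 down) genes passing, and 3 of the 84 given by the naming rule kept their call. With the endothelial score too, chosen after seeing the data, 4 (1 up, 3 down) passed. Leaving out 1 library moved the count of 2378 by more than 1.5 times without control replicates 2 (1324, 603 up) and 6 (1579, 737 up) and Rbpj-/- replicates 1 (1403, 691 up), 2 (1132) and 4 (1255). More genes fell than rose with the size factors of DESeq2 (1226 and 1051), the DESeq2 test (1719 and 1378) and no filter (1000 and 921). The count was 1533 (717 up, 816 down) with a stricter filter, 3747 (1853 up, 1894 down) with voom, 1222 (346 up, 876 down) with only these libraries in the fit and 1492 (672 up, 820 down) without the 3 mixed libraries, chosen after seeing the data.

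The second comparison asked what changes when both receptors are lost. Hes5 fell to 0.628 ± 0.327 CPM (n = 5) from 4.09 ± 2.05 CPM (n = 6), and Nrarp, a feedback inhibitor of Notch, to 5.61 ± 1.77 from 23.1 ± 6.72 CPM. Some mural and most astrocyte, microglia, endothelial and mature oligodendrocyte genes fell, and most cell cycle genes rose. The fetal imprinted RNA H19 rose from 4.63 ± 3.27 to 200.2 ± 144 CPM. Of 15617 genes tested with edgeR, 2855 rose and 2939 fell. Of these, 114 of the 116 named by rule, which selects for it, were on the same side of the control median in 5 of 5 libraries.

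Among Notch genes, 5 of 10 targets fell (5 list-wise, camera adjusted p = 0.0112, or 0.360 estimated). Hes5 (-2.69 ± 0.41), Nrarp (-2.04 ± 0.33), Hes1 (-2.44 ± 0.42) and Hey1 (-1.15 ± 0.20) fell, with adjusted p of 6.91e-05 to 1.80e-04. 4 of 22 pathway components rose and 5 fell (4 rose and 7 fell list-wise, camera adjusted p = 0.658). Dll3 (1.15 ± 0.15) rose, with adjusted p = 1.57e-05. In the proneural and early neuronal list, 4 of 13 genes rose and 1 fell (the same counts list-wise, camera adjusted p = 0.623). The neuronal transcription factor Sox11 (1.40 ± 0.28) and the surface protein Cd24a (1.67 ± 0.47) rose, with adjusted p of 6.43e-04 to 0.00819. In the astrocyte list, 13 of 20 genes fell (1 rose and 13 fell list-wise, camera adjusted p = 3.86e-06, or 0.108 estimated). Glul (-1.37 ± 0.17), Mlc1 (-3.45 ± 0.43), the glycolytic enzyme Aldoc (-1.59 ± 0.21) and the chaperone Clu (-1.63 ± 0.23) fell, with adjusted p of 8.72e-06 to 2.57e-05. In the neural stem and progenitor list, 3 of 17 genes rose and 3 fell (2 rose and 2 fell list-wise, camera adjusted p = 0.874). Prom1 (-3.02 ± 0.47) and the fatty acid binding protein Fabp7 (-1.18 ± 0.25) fell, with adjusted p of 8.02e-05 to 0.00104. Sox2, a transcription factor of stem cells, rose (0.55 ± 0.14, adjusted p = 0.00367). In the oligodendrocyte precursor list, 1 of 18 genes rose and 1 fell (the same counts list-wise, camera adjusted p = 0.706). They were Sox6 (0.82 ± 0.19, adjusted p = 0.00201) and Olig1 (-0.61 ± 0.18, adjusted p = 0.0109). In the mature neuron list, 1 of 16 genes rose and 4 fell (the same counts list-wise, camera adjusted p = 0.0294, or 0.738 estimated). Mature neuron lost its call without Notch1-/-Notch2-/- replicates 2 (0.0510) and 4 (0.0700) and control replicate 4 (0.0629).

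In the cell cycle list, 21 of 30 genes rose (24 rose list-wise, camera adjusted p = 3.86e-06, or 0.738 estimated). In the immediate early and dissociation stress list, 7 of 21 genes rose and 2 fell (7 rose and 4 fell list-wise, camera adjusted p = 0.233). The AP-1 genes Jun (1.40 ± 0.17), Fos (2.15 ± 0.35) and Fosb (3.09 ± 0.58) rose, with adjusted p of 6.27e-06 to 3.79e-04. In the p53 target list, 2 of 16 genes rose and 4 fell (the same counts list-wise, camera adjusted p = 0.917). The death receptor Tnfrsf10b was among the former (3.06 ± 0.48, adjusted p = 8.37e-05). In the MAPK output list, 1 of 17 genes rose and 2 fell (1 rose and 1 fell list-wise, camera adjusted p = 0.917). The ERK phosphatase Dusp6 was among the latter (-1.03 ± 0.27, adjusted p = 0.00466). In the hypoxia list, 3 of 18 genes rose and 2 fell (the same counts list-wise, camera adjusted p = 0.752). In the mesenchymal glioma list, 5 of 20 genes rose and 1 fell (the same counts list-wise, camera adjusted p = 0.582). Cd44 stood at 3.45 ± 0.89 (adjusted p = 0.00433).

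In the BMP and Id list, 1 of 13 genes rose and 3 fell (the same counts list-wise, camera adjusted p = 0.582). Id4 (-2.61 ± 0.34) and Bmp2 (-1.66 ± 0.32) fell, with adjusted p of 1.55e-05 to 5.26e-04. In the Wnt target list, 1 of 11 genes rose and 4 fell (the same counts list-wise, camera adjusted p = 0.173). The Wnt transcription factor Lef1 stood at -2.48 ± 0.62 (adjusted p = 0.00359). In the YAP and TEAD target list, 2 of 10 genes rose (2 list-wise, camera adjusted p = 0.582). In cholesterol biosynthesis, 8 of 19 genes fell (10 fell list-wise, camera adjusted p = 0.0149, or 0.738 estimated). Among the largest changes, H19 (5.44 ± 0.98), Dlk1 (3.66 ± 0.84), the acute phase gene Serpina3n (3.74 ± 0.73) and the meiotic helicase Hfm1 (4.14 ± 0.48) rose, with adjusted p of 4.71e-06 to 0.00193. Trnp1 (-4.63 ± 0.42) and the thyroid hormone transporter Slco1c1 (-4.33 ± 0.50) fell, with adjusted p of 3.58e-07 to 4.71e-06.

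Markers of other cell types moved with these groups too. Of microglia and macrophages, 19 of 21 genes fell (20 fell list-wise, camera adjusted p = 1.01e-13, or 0.360 estimated). P2ry12 (-3.85 ± 0.48), Siglech (-4.20 ± 0.47) and the lipid receptor Trem2 (-3.70 ± 0.51) fell, with adjusted p of 3.97e-06 to 2.17e-05. Of the endothelium, 13 of 15 genes fell (13 list-wise, camera adjusted p = 5.26e-06, or 0.536 estimated). Tek (-3.55 ± 0.52), the tight junction gene Cldn5 (-3.34 ± 0.59) and Slco1a4 (-4.42 ± 0.68) fell, with adjusted p of 4.31e-05 to 2.30e-04. Of mural cells and fibroblasts, 4 of 14 genes fell (4 list-wise, camera adjusted p = 0.00774, or 0.738 estimated). Vtn (-4.15 ± 0.58) and Rgs5 (-3.17 ± 0.54) fell, with adjusted p of 2.57e-05 to 1.50e-04. Of mature oligodendrocytes, 12 of 16 genes fell (12 list-wise, camera adjusted p = 3.86e-06, or 0.718 estimated). Mog (-4.21 ± 0.70), Mal (-4.77 ± 0.80) and Aspa (-4.33 ± 0.73) fell, with adjusted p of 1.37e-04 to 1.46e-04. Of infiltrating myeloid cells, 1 of 10 genes rose and 4 fell (the same counts list-wise, camera adjusted p = 0.165). Of T and NK cells, 1 of 10 genes fell (1 list-wise, camera adjusted p = 0.658). Of B cells, 1 of 3 genes rose and 2 fell (the same counts list-wise, camera adjusted p = 0.582). Of ependymal cells, 1 of 5 genes rose and 1 fell (1 rose and 2 fell list-wise, camera adjusted p = 0.781). Of erythroid cells, 1 of 7 genes fell (5 fell list-wise, camera adjusted p = 0.0170, or 0.738 estimated). Infiltrating myeloid was called without Notch1-/-Notch2-/- replicates 4 (0.0424) and 5 (0.0378). Erythroid lost its call without Notch1-/-Notch2-/- replicate 5 (0.0556).

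In the MHC class I list, 0 of 22 genes passed with edgeR, 2 at an unadjusted p under 0.05, 2 with DESeq2 and 4 with voom (0 list-wise, camera adjusted p = 0.0294, or 0.816 estimated). In the MHC class II list, 3 of 10 genes fell (2 fell list-wise, camera adjusted p = 0.0170, or 0.738 estimated). In the interferon gamma list, 0 of 29 genes passed with edgeR, 0 at an unadjusted p under 0.05, 0 with DESeq2 and 4 with voom (0 list-wise, camera adjusted p = 0.0170, or 0.816 estimated). The immunity-related GTPase gene Irgm1 stood at -0.72 ± 1.01 (adjusted p = 0.602). In the type I interferon list, 1 of 26 genes fell (0 list-wise, camera adjusted p = 0.168). Among interferon receptors and signalling, 1 of 12 genes rose and 2 fell (the same counts list-wise, camera adjusted p = 0.917). The kinase Jak1 stood at -0.51 ± 0.13 (adjusted p = 0.00517). Of cytokines and chemokines, 10 of 23 genes fell (10 list-wise, camera adjusted p = 0.0170, or 0.718 estimated). The chemokine Cxcl5 (-5.37 ± 0.74) fell, with adjusted p = 2.18e-05. MHC class I antigen presentation lost its call without control replicates 2 (0.0529), 3 (0.0602), 4 (0.0544) and 6 (0.0904) and Notch1-/-Notch2-/- replicates 1 (0.135), 2 (0.121) and 3 (0.141). MHC class II antigen presentation lost its call without Notch1-/-Notch2-/- replicate 3 (0.0663). Interferon gamma response lost its call without Notch1-/-Notch2-/- replicates 1 (0.0650), 2 (0.0510) and 3 (0.0912). Type I interferon response was called without control replicate 1 (0.00417) and Notch1-/-Notch2-/- replicates 4 (0.0204) and 5 (0.0378). Cytokines and chemokines lost its call without Notch1-/-Notch2-/- replicate 3 (0.0581). With the microglia and macrophage score as a covariate camera's direction turned, at mean log2 fold changes (camera adjusted p) of 1.77 (0.0316) for MHC class I, 2.87 (0.121) for MHC class II, 2.17 (0.0190) for interferon gamma, 1.94 (0.00169) for type I interferon and 3.21 (0.00615) for T and NK cells.

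Scores of other cell types differed from control by -3.12 for microglia and macrophage, -2.34 for endothelial, -2.04 for mural and fibroblast, -2.52 for mature oligodendrocyte, -0.86 for mature neuron and -1.68 for erythroid (p = 0.00216 to 0.0216, adjusted p = 0.00487 to 0.0325, exact two-sided permutation over 462 splits). Added as a covariate, the microglia and macrophage score left 579 (234 up, 345 down) genes passing, and 30 of the 116 given by the naming rule kept their call. With the endothelial score too, chosen after seeing the data, 39 (13 up, 26 down) passed. More genes rose than fell without a filter (2836 and 2832) and with voom (3686 and 3678). Median, mean and camera direction differed in sign for the proneural and early neuronal list (median -0.01, mean 0.12, camera direction higher), the p53 target genes list (median 0.01, mean 0.07, camera direction lower), the MAPK output list (median 0.00317, mean 0.20, camera direction lower) and the interferon receptors and signalling list (median -0.12, mean 0.05, camera direction lower). The median of all genes moved by -0.00717 under the size factors of DESeq2, and the medians of the p53 target and MAPK output lists changed sign.

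**Figure D2:**
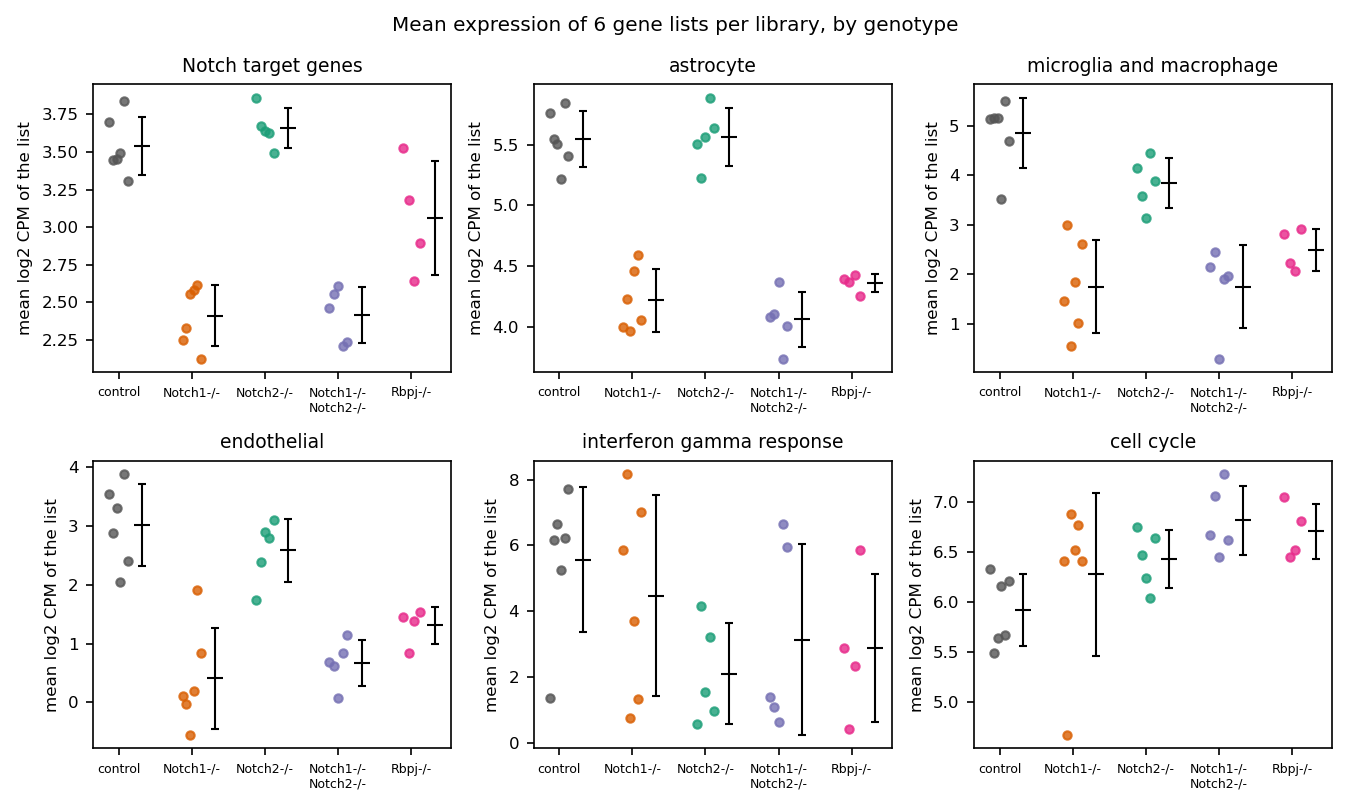
Mean log2 CPM (y axis) of the Notch target, astrocyte, microglia and macrophage, endothelial, interferon gamma response and cell cycle lists in the 26 libraries (points), by genotype (x axis), with the mean and standard deviation in black. The microglia and macrophage list lies at 4.86 ± 0.71 in control, 3.84 ± 0.51 in Notch2-/-, 1.75 ± 0.94 in Notch1-/-, 1.75 ± 0.84 in Notch1-/-Notch2-/- and 2.50 ± 0.42 in Rbpj-/-.

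Loss of Notch1 alone was compared with control next. Hes5 fell to 0.514 ± 0.149 CPM (n = 6) from 4.09 ± 2.05 CPM (n = 6), and Nrarp to 6.55 ± 3.27 from 23.1 ± 6.72 CPM. Some astrocyte and mural and most microglia, endothelial and mature oligodendrocyte genes fell, and neuronal Sox11 and Sox4 rose. Of 15617 genes tested with edgeR, 2058 rose and 2116 fell. Of these, 78 of the 98 named by rule, which selects for it, were on the same side of the control median in 6 of 6 libraries.

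Among Notch genes, 6 of 10 targets fell (6 list-wise, camera adjusted p = 0.00165, or 0.139 estimated). Hes5 (-2.99 ± 0.39), Nrarp (-1.82 ± 0.30), Hey1 (-0.99 ± 0.19) and Lfng (-1.55 ± 0.45) fell, with adjusted p of 5.85e-05 to 0.0158. 4 of 22 pathway components rose and 1 fell (the same counts list-wise, camera adjusted p = 0.534). The ligand Dll4 (-2.37 ± 0.40) fell, with adjusted p = 4.49e-04. The ligand Jag1 (1.08 ± 0.28) rose, with adjusted p = 0.00807. Jag1 stood at -0.18 (adjusted p = 0.857) with the microglia and macrophage score as a covariate, and Dll4 at 0.0525 (adjusted p = 0.991) with the endothelial score as well, chosen after seeing the data. In the proneural and early neuronal list, 3 of 13 genes rose (3 list-wise, camera adjusted p = 0.187). Sox11 (1.23 ± 0.27) and Sox4 (0.66 ± 0.17) rose, with adjusted p of 0.00287 to 0.00915. In the astrocyte list, 10 of 20 genes fell (11 fell list-wise, camera adjusted p = 1.89e-07, or 0.0492 estimated). Mlc1 (-2.58 ± 0.38), Glul (-1.07 ± 0.16), Slc4a4 (-1.93 ± 0.30) and Aqp4 (-2.57 ± 0.42) fell, with adjusted p of 1.48e-04 to 2.88e-04. In cholesterol biosynthesis, 7 of 19 genes fell (9 fell list-wise, camera adjusted p = 0.00221, or 0.556 estimated). In the cell cycle list, 4 of 30 genes rose (0 list-wise, camera adjusted p = 0.0444, or 0.765 estimated). Cell cycle lost its call without control replicates 2 (0.141) and 5 (0.139) and Notch1-/- replicates 1 (0.0730), 3 (0.198), 4 (0.122), 5 (0.241) and 6 (0.0604). With the microglia and macrophage score as a covariate its mean log2 fold change was -0.33 (camera adjusted p = 0.0383). Among the largest rises, the chromatin protein Hmga2 (3.59 ± 0.98), the exchange factor Tiam2 (2.89 ± 0.61) and H19 (3.28 ± 0.88) rose, with adjusted p of 0.00217 to 0.0107.

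Of microglia and macrophages, 20 of 21 genes fell (21 fell list-wise, camera adjusted p = 1.01e-18, or 0.150 estimated). Trem2 (-4.19 ± 0.48) and P2ry12 (-3.12 ± 0.43) fell, with adjusted p of 1.42e-05 to 6.27e-05. Of the endothelium, 12 of 15 genes fell (13 fell list-wise, camera adjusted p = 6.45e-09, or 0.150 estimated). Tek (-3.66 ± 0.49) and Slco1a4 (-4.02 ± 0.62) fell, with adjusted p of 5.85e-05 to 1.97e-04. Of mural cells and fibroblasts, 5 of 14 genes fell (6 fell list-wise, camera adjusted p = 1.40e-05, or 0.296 estimated). Vtn (-3.51 ± 0.52) and Rgs5 (-3.26 ± 0.50) fell, with adjusted p of 1.48e-04 to 1.81e-04. Of mature oligodendrocytes, 10 of 16 genes fell (12 fell list-wise, camera adjusted p = 1.70e-06, or 0.441 estimated). Mog (-2.58 ± 0.60) and Aspa (-2.61 ± 0.62) fell, with adjusted p of 0.00429 to 0.00477. Of infiltrating myeloid cells, 4 of 10 genes fell (4 list-wise, camera adjusted p = 0.0225, or 0.466 estimated). In the MHC class II list, 2 of 10 genes fell (1 fell list-wise, camera adjusted p = 0.0243, or 0.765 estimated). Of cytokines and chemokines, 1 of 23 genes rose and 10 fell (1 rose and 12 fell list-wise, camera adjusted p = 1.19e-04, or 0.150 estimated). Of erythroid cells, 0 of 7 genes passed with edgeR, 5 at an unadjusted p under 0.05, 5 with DESeq2 and 5 with voom (5 fell list-wise, camera adjusted p = 0.00343, or 0.524 estimated). Of B cells, 2 of 3 genes fell (2 list-wise, camera adjusted p = 0.225). Infiltrating myeloid lost its call without Notch1-/- replicate 5 (0.0501). MHC class II antigen presentation lost its call without Notch1-/- replicates 3 (0.0820) and 5 (0.217). With the microglia and macrophage score as a covariate camera's direction turned, at mean log2 fold changes (camera adjusted p) of 1.38 (0.472) for infiltrating myeloid cells and 4.80 (2.19e-04) for MHC class II.

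Scores of other cell types differed from control by -3.12 for microglia and macrophage, -1.69 for infiltrating myeloid, -2.60 for endothelial, -2.61 for mural and fibroblast, -1.81 for mature oligodendrocyte and -1.80 for erythroid (p = 0.00216 to 0.0130, adjusted p = 0.00974 to 0.0195, exact two-sided permutation over 924 splits). Added as a covariate, the microglia and macrophage score left 15 (7 up, 8 down) genes passing, and 3 of the 98 given by the naming rule kept their call. With the endothelial score too, chosen after seeing the data, 3 (0 up, 3 down) passed. With voom, 6907 (3468 up, 3439 down) genes passed.

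Loss of Notch2 alone was compared with control in the same way. The calcium-binding genes S100a3 (-2.68 ± 0.40), S100a6 (-2.27 ± 0.41) and the splicing factor Scnm1 (-1.34 ± 0.21) fell, with adjusted p of 0.00225 to 0.00966. The germ line cyclin Ccna1 (2.70 ± 0.34) and Hfm1 (2.93 ± 0.46) rose, with adjusted p of 5.47e-04 to 0.00331. The ribosomal protein genes Rps2 (5.05 ± 0.81) and Rpl30 (1.56 ± 0.23) rose as well, with adjusted p of 0.00225 to 0.00369. Reads of ribosomal protein genes can be split among near-identical copies. Of 15617 genes tested with edgeR, 20 rose and 26 fell, with 2315 at an unadjusted p under 0.05. Of these, 21 of the 21 named by rule, which selects for it, were on the same side of the control median in 5 of 5 libraries.

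Hes5 stood at 6.44 ± 2.45 CPM (n = 5) against 4.09 ± 2.05 CPM (n = 6), and Nrarp at 34.1 ± 5.61 against 23.1 ± 6.72 CPM. 0 of 10 Notch targets passed with edgeR, 2 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with voom (0 list-wise, camera adjusted p = 0.433). 0 of 20 astrocyte genes passed with edgeR, 1 at an unadjusted p under 0.05, 0 with DESeq2 and 1 with voom (0 list-wise, camera adjusted p = 0.969). 0 of 10 MHC class II genes passed with edgeR, 9 at an unadjusted p under 0.05, 9 with DESeq2 and 4 with voom (9 lower list-wise, camera adjusted p = 8.53e-07, or 0.415 estimated). H2-Ab1 stood at -6.25 ± 1.57 (adjusted p = 0.0962). 0 of 29 interferon gamma response genes passed with edgeR, 23 at an unadjusted p under 0.05, 8 with DESeq2 and 3 with voom (23 lower list-wise, camera adjusted p = 4.13e-10, or 0.415 estimated). Irgm1 stood at -2.86 ± 1.10 (adjusted p = 0.261). 0 of 22 MHC class I genes passed with edgeR, 17 at an unadjusted p under 0.05, 13 with DESeq2 and 6 with voom (17 lower list-wise, camera adjusted p = 4.13e-10, or 0.415 estimated). 0 of 26 type I interferon response genes passed with edgeR, 15 at an unadjusted p under 0.05, 7 with DESeq2 and 2 with voom (13 lower list-wise, camera adjusted p = 4.91e-09, or 0.415 estimated). 1 of 10 T and NK cell genes fell (7 fell list-wise, camera adjusted p = 4.42e-04, or 0.415 estimated). It was the chemokine Ccl5 (-4.51 ± 0.94, adjusted p = 0.0305), a call that ended without control replicates 2 (0.0709), 3 (0.0606), 5 (0.0564) and 6 (0.0721) and Notch2-/- replicates 1 (0.0917), 2 (0.104), 3 (0.0699), 4 (0.0733) and 5 (0.118).

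0 of 21 microglia and macrophage genes passed with edgeR, 10 at an unadjusted p under 0.05, 6 with DESeq2 and 10 with voom (10 lower list-wise, camera adjusted p = 4.13e-10, or 0.415 estimated). Ctss stood at -2.22 ± 0.62 (adjusted p = 0.146). 0 of 30 cell cycle genes passed with edgeR, 7 at an unadjusted p under 0.05, 1 with DESeq2 and 9 with voom (0 list-wise, camera adjusted p = 8.53e-07, or 0.487 estimated). Camera called 12 of 32 lists lower and 3 higher, and 0 with an estimated correlation. Of other lists, camera called with all libraries and without each (adjusted p) mature oligodendrocyte (3.81e-06), cytokines and chemokines (3.23e-04) and hypoxia (1.42e-04) lower and neural stem and progenitor (2.60e-04) and MAPK output (0.00124) higher. The microglia and macrophage score differed from control by -1.03 and the T and NK cell score by -1.63 (exact two-sided permutation p = 0.0303 and 0.0281 over 462 splits, adjusted p = 0.0909 and 0.0909).

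Added as a covariate, the microglia and macrophage score left 17 (10 up, 7 down) genes passing, and 9 of the 21 given by the naming rule kept their call. With the endothelial score too, chosen after seeing the data, 24 (14 up, 10 down) passed. Leaving out 1 library moved the count of 46 by more than 1.5 times without control replicates 2 (24), 3 (26), 4 (83) and 5 (28) and Notch2-/- replicates 1 (22, 12 up), 2 (23, 14 up), 4 (23, 13 up) and 5 (21, 12 up). Passing genes numbered 343 (84 up, 259 down) with DESeq2, 1790 (845 up, 945 down) with voom, 16 (7 up, 9 down) with a stricter filter, 182 (35 up, 147 down) with only these libraries in the fit and 12 (8 up, 4 down) without the 3 mixed libraries, chosen after seeing the data. Median, mean and camera direction differed in sign for the astrocyte list (median 0.06, mean -0.01, camera direction higher).

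**Figure D3:**
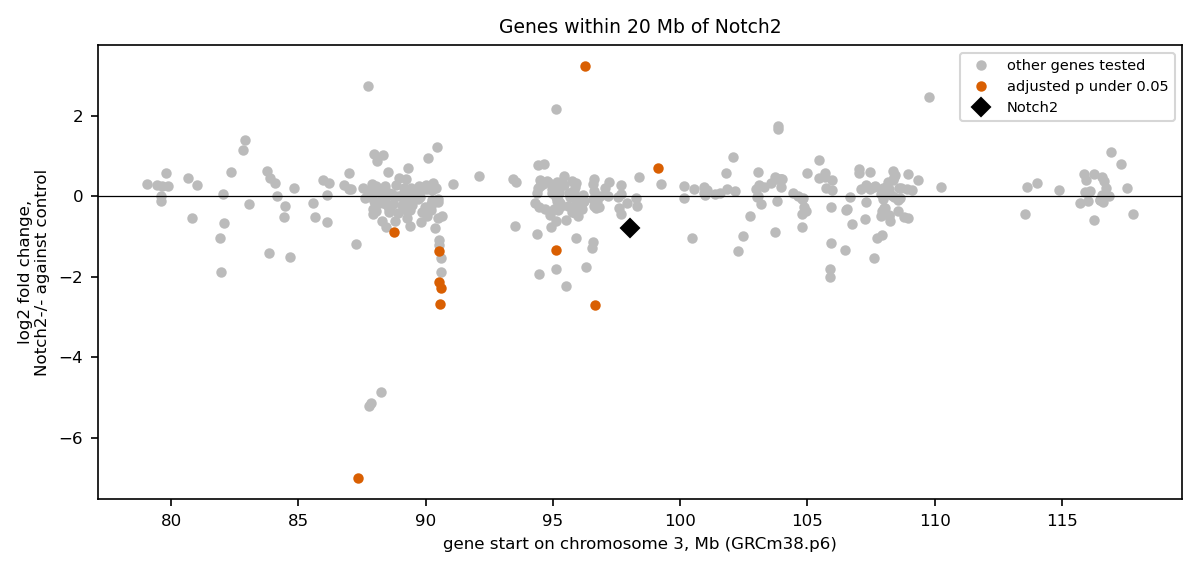
Log2 fold change of Notch2-/- against control (y axis) of genes that start within 20 Mb of Notch2 on chromosome 3 (x axis, Mb, GRCm38.p6), with Notch2 as a black diamond and genes with an adjusted p under 0.05 in orange. 10 of 379 of these genes passed, against 36 of 15238 other genes, with which Notch2 itself was counted.

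Whether loss of Rbpj differs from loss of both receptors was tested directly. Unc5d was higher in Rbpj-/-, at 24.7 ± 10.4 CPM (n = 4) against 0.811 ± 0.264 CPM (n = 5; log2 fold change 4.92 ± 0.62, adjusted p = 1.92e-04). The oxidoreductase-like gene Cryzl2 (2.13 ± 0.33) was also higher, with adjusted p = 0.00153. The neuronal gene Dpysl5 (-1.75 ± 0.29) was lower, with adjusted p = 0.00430. Of 15617 genes tested with edgeR, 68 were higher and 56 lower in Rbpj-/-. Of these, 26 of the 26 named by rule, which selects for it, were on the same side of the Notch1-/-Notch2-/- median in 4 of 4 libraries.

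Of Notch targets, 2 of 10 genes were higher (5 higher list-wise, camera adjusted p = 0.00445, or 0.186 estimated). They were Nrarp (1.65 ± 0.35, adjusted p = 0.0241), a call that ended without Rbpj-/- replicates 1 (0.0916) and 2 (0.0687) and Notch1-/-Notch2-/- replicates 2 (0.0758), 4 (0.0802) and 5 (0.0638), and Hey1 (0.95 ± 0.21, adjusted p = 0.0354), a call that ended without Notch1-/-Notch2-/- replicates 1 (0.0750), 2 (0.107), 4 (0.0999) and 5 (0.0749) and Rbpj-/- replicates 1 (0.134), 2 (0.0702) and 3 (0.0617). Nrarp had 17.6 ± 5.22 CPM in Rbpj-/- and 5.61 ± 1.77 CPM in Notch1-/-Notch2-/-. Rbpj itself was lower (-1.03 ± 0.21, adjusted p = 0.0197), a call that ended without Rbpj-/- replicates 1 (0.0550) and 2 (0.0687) and Notch1-/-Notch2-/- replicates 2 (0.0569) and 4 (0.0571). 0 of 21 microglia and macrophage genes passed with edgeR, 3 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with voom (0 list-wise, camera adjusted p = 0.0132, or 0.971 estimated). 0 of 17 MAPK output genes passed with edgeR, 4 at an unadjusted p under 0.05, 1 with DESeq2 and 0 with voom (0 list-wise, camera adjusted p = 0.0318, or 0.971 estimated). Microglia and macrophage lost its call without Notch1-/-Notch2-/- replicate 3 (0.329) and Rbpj-/- replicate 4 (0.138). MAPK output lost its call without Rbpj-/- replicates 1 (0.0605) and 2 (0.0963) and Notch1-/-Notch2-/- replicate 4 (0.117).

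Leaving out 1 library moved the count of 124 by more than 1.5 times without Notch1-/-Notch2-/- replicates 1 (81), 2 (34, 15 up), 4 (35) and 5 (54) and Rbpj-/- replicates 1 (42), 2 (21) and 4 (75). With the size factors of DESeq2, 53 were higher and 55 lower. Passing genes numbered 81 (42 up, 39 down) without a filter, 73 (39 up, 34 down) with a stricter one, 313 (158 up, 155 down) with DESeq2, 31 (10 up, 21 down) with only these libraries in the fit and 76 (37 up, 39 down) without the 3 mixed libraries, chosen after seeing the data.

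The single losses were also compared with each other. Hes5 was lower in Notch1-/- (0.514 ± 0.149 CPM, n = 6) than in Notch2-/- (6.44 ± 2.45 CPM, n = 5), as was Nrarp (6.55 ± 3.27 against 34.1 ± 5.61 CPM). Some astrocyte, microglia, endothelial and mural genes were lower in Notch1-/-. Notch2 itself was higher in Notch1-/- (1.02 ± 0.16, adjusted p = 3.98e-04). Of 15617 genes tested with edgeR, 131 were higher and 351 lower in Notch1-/-. Of these, 47 of the 49 named by rule, which selects for it, were on the same side of the Notch2-/- median in 6 of 6 libraries.

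Of Notch targets, 5 of 10 genes were lower (6 lower list-wise, camera adjusted p = 1.31e-06, or 0.00595 estimated). Hes5 (-3.64 ± 0.41), Nrarp (-2.38 ± 0.32) and Lfng (-2.57 ± 0.48) were lower, with adjusted p of 1.27e-05 to 0.00288. Of astrocytes, 9 of 20 genes were lower (13 lower list-wise, camera adjusted p = 6.99e-14, or 0.00147 estimated). Slc4a4 (-2.20 ± 0.31), Mlc1 (-2.52 ± 0.39), Aqp4 (-2.51 ± 0.43) and the neurotensin receptor Ntsr2 (-1.73 ± 0.29) were lower, with adjusted p of 2.15e-04 to 0.00125. Of microglia and macrophages, 10 of 21 genes were lower (19 lower list-wise, camera adjusted p = 3.76e-19, or 0.110 estimated). P2ry12 (-3.14 ± 0.43) and Trem2 (-3.03 ± 0.47) were lower, with adjusted p of 1.59e-04 to 5.33e-04. Of the endothelium, 8 of 15 genes were lower (1 higher and 10 lower list-wise, camera adjusted p = 1.45e-11, or 0.110 estimated). Tek (-3.44 ± 0.49) and the VEGF receptor Flt1 (-3.00 ± 0.56) were lower, with adjusted p of 2.27e-04 to 0.00302. Of mural cells and fibroblasts, 5 of 14 genes were lower (5 list-wise, camera adjusted p = 1.72e-06, or 0.214 estimated). Rgs5 (-3.39 ± 0.51) and Vtn (-2.74 ± 0.52) were lower, with adjusted p of 3.98e-04 to 0.00305.

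The MHC class I list and both interferon response lists were higher in Notch1-/- than in Notch2-/- by camera (adjusted p = 1.84e-04, or 0.574 estimated, for type I interferon), and the MHC class II list was not called (adjusted p = 0.131). 1 of 22 MHC class I genes was higher (19 higher list-wise, camera adjusted p = 1.39e-04, or 0.574 estimated). 0 of 29 interferon gamma response genes passed with edgeR, 24 at an unadjusted p under 0.05, 19 with DESeq2 and 0 with voom (23 higher list-wise, camera adjusted p = 2.92e-05, or 0.574 estimated). 0 of 10 T and NK cell genes passed with edgeR, 9 at an unadjusted p under 0.05, 3 with DESeq2 and 0 with voom (8 higher list-wise, camera adjusted p = 0.00427, or 0.546 estimated). Of other lists, camera called with all libraries and without each (adjusted p) mature neuron (0.00804, or 0.516 estimated), cytokines and chemokines (0.00475, or 0.345 estimated) and cholesterol biosynthesis (6.19e-08, or 0.226 estimated) lower. T and NK cell lost its call without Notch1-/- replicate 2 (0.0790). MHC class II antigen presentation was called without Notch1-/- replicates 3 (0.0224) and 5 (0.0130). The T and NK cell score was -2.0 ± 1.59 in Notch1-/- and -3.35 ± 0.13 in Notch2-/-.

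As a covariate, the microglia and macrophage score gave 428 higher and 193 lower genes, 621 in all, with 174 of the 482 kept, so that the larger side turned. 8 (0 up, 8 down) passed with the endothelial score too, chosen after seeing the data. Leaving out 1 library moved the count of 482 by more than 1.5 times without Notch1-/- replicates 1 (275) and 5 (841) and Notch2-/- replicates 3 (310), 4 (293) and 5 (284). Passing genes numbered 193 (61 up, 132 down) with a stricter filter, 1097 (455 up, 642 down) with DESeq2, 1904 (701 up, 1203 down) with voom, 294 (42 up, 252 down) with only these libraries in the fit, 301 (65 up, 236 down) with Xist as a covariate and 142 (17 up, 125 down) without the 3 mixed libraries, chosen after seeing the data.

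The interaction asked whether loss of both receptors departs from the sum of the single losses on the log2 scale. Unc5d stood at 3.01 ± 1.65 CPM in control, 10.6 ± 6.49 in Notch1-/-, 12.2 ± 11.6 in Notch2-/- and 0.811 ± 0.264 in Notch1-/-Notch2-/-, below the sum (-5.71 ± 0.76, adjusted p = 0.00130). The membrane-binding protein Cpne8 (-2.86 ± 0.49), the microtubule-associated gene Mtus1 (-2.21 ± 0.37) and Rps2 (-7.74 ± 1.12) lay below the sum as well, with adjusted p of 0.00276 to 0.0156. Among 15617 genes tested with edgeR, 3 lay above the sum and 9 below (75.0% below, and 64.3% with the size factors of DESeq2), and 2013 departed from it at an unadjusted p under 0.05. Leaving out 1 library moved the count of 12 by more than 1.5 times without Notch2-/- replicates 1 (7) and 2 (6), Notch1-/- replicates 2 (227, 131 above) and 4 (7) and Notch1-/-Notch2-/- replicates 2 (5), 3 (28, 15 above) and 4 (6). Passing genes numbered 139 (84 above, 55 below) with DESeq2, 924 (441 above, 483 below) with voom, 7 (2 above, 5 below) with the microglia and macrophage score, 7 (1 above, 6 below) with Xist as a covariate and 5 (0 above, 5 below) without the 3 mixed libraries, chosen after seeing the data.

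The effects of losing Rbpj and of losing both receptors were compared across genes, which are not independent replicates. Of 15617 genes, 982 rose in both and 1039 fell in both, 2 passed in opposite directions, and independent lists would share 228 and 213. The log2 fold changes correlated at r = 0.820 (covariance 0.721); unchanged groups simulated against the same controls gave a mean r of 0.418 and covariance of 0.0690 over 40 simulations, a difference in covariance of 0.652. With the controls split between the comparisons in 20 ways, r was 0.663 to 0.754, and a median of 178 genes rose and 359 fell in both. Notch1-/- and Notch2-/- shared 15 rises and 16 falls, with 1 gene passing in opposite directions, where independent lists would share 2.64 and 3.52. Their r was 0.495 beside a simulated mean of 0.473, their covariance 0.285 beside 0.0687, and r was 0.247 to 0.535 with split controls, where a median of 2 genes rose and 1 fell in both. For Notch1-/- and Notch1-/-Notch2-/-, a pair chosen after seeing the data, 1642 genes rose and 1720 fell in both, 5 passed in opposite directions and independent lists would share 376 and 398. There r was 0.840 beside a simulated mean of 0.475, the covariance 0.719 beside 0.0690, and r 0.668 to 0.788 with split controls, with medians of 458 and 826.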

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

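The test of a lower share of all other cells alike, those of flanking DNA around Notch2 and around Notch1, and the correlations on either side of a gap were chosen only after the result was seen.

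In 11 of 85 groups of values tested, the highest or lowest library of a genotype stood farther from its neighbour than Dixon's criterion allows, where chance gives about 1 in 20 groups, or 4.25. Trp53 was highest in control replicate 3 (15.2 CPM). Xist was highest in control replicate 1 (1624 CPM), Notch1-/- replicate 5 (2.04 CPM), Notch2-/- replicate 4 (1918 CPM) and Rbpj-/- replicate 2 (3465 CPM). As mean log2 CPM, the microglia and macrophage score was lowest in Notch1-/-Notch2-/- replicate 3 (0.29). The mature oligodendrocyte score was lowest in control replicate 4 (7.98) and highest in Notch1-/- replicate 2 (8.95) and Rbpj-/- replicate 3 (7.79). The MHC class I score was lowest in control replicate 1 (3.56), and the cell cycle score in Notch1-/- replicate 2 (4.66).

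The effects of genotypes differed in direct tests: 124 genes between Rbpj-/- and Notch1-/-Notch2-/-, 482 between Notch1-/- and Notch2-/-, and 12 in the interaction. Of 100 splits of the libraries into groups of the same sizes, the real one included, 3, 2 and 2 gave as many genes, with 783, 627 and 28 at most in the others. For the losses of Rbpj, of both receptors, of Notch1 and of Notch2 against control, with 2378, 5794, 4174 and 46 genes, 2, 1, 2 and 3 of 100 splits gave as many, with 2668, 34, 4612 and 2963 at most in the others. Chance is thus only disfavoured for these 7 counts. Splits that called 2963 genes where the real one called 46, and 783 where it called 124, point to a structure of the samples other than genotype.

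Markers of other cell types were lower in Rbpj-/-, Notch1-/- and Notch1-/-Notch2-/- libraries although all were of sorted GFP-positive cells: from control to Notch1-/-Notch2-/-, Ctss, among the most abundant of 21 microglia and macrophage genes, went from 305 ± 158 to 17.8 ± 8.73 CPM, and the endothelial gene Ramp2 from 31.2 ± 6.67 to 14.9 ± 3.06 CPM, while the endothelial gene Vwf went the other way, from 14.1 ± 3.52 to 20.6 ± 5.29 CPM. A lower share of all other cells alike cannot be told apart: relative to the endothelial score (0 genes shared), the microglia and macrophage score changed by -0.78 in Notch1-/-Notch2-/-, -0.66 in Rbpj-/- and -0.51 in Notch1-/- (log2 scale, exact permutation p = 0.0260, 0.0143 and 0.444), but by the median gene of each list by -0.43, -0.38 and -0.0946 (exact p = 0.348, 0.381 and 0.920). Against mural and fibroblast only Notch1-/-Notch2-/- differed (-1.08, adjusted exact p = 0.0242), against mature oligodendrocyte only Notch1-/- (-1.30, 0.0104), where it stays too high (7.08 ± 0.99). Infiltrating myeloid (-1.43, 0.00866 in Notch1-/-) lies too near the floor (0.72 ± 0.72 in control). Leukocyte RNA as the whole of the lower astrocyte list in Notch1-/- cannot be told apart, since the microglia score differs mostly between genotypes. With it in the fit the list's mean log2 fold change went from -1.35 to -0.95 (camera adjusted p = 7.84e-05). A sort purity that varies between libraries of 1 genotype cannot be told apart. In control the mature oligodendrocyte score (8.90) was near that of precursors (9.03), so its genes may be the tumour cells' own. Within genotypes that score gave r = 0.195 with the microglia score (rho = 0.106, permutation p = 0.385 and 0.628, n = 26). Fewer such cells in these tumours, as an effect of the genotype, stay open and untested.

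Interferon gamma response genes varied between libraries of 1 genotype, with scores of 5.56 ± 2.20 in control and 4.47 ± 3.05 in Notch1-/- libraries, and the depth of the libraries is argued against as the whole source, with r = 0.0771 within genotypes (rho = 0.0126, permutation p = 0.736 and 0.956, also after adjustment over 4 relations; r = -0.199 without Rbpj-/- replicate 2 and Notch1-/- replicate 3). T and NK cells in the tumours, which a sort for GFP would remove, are a candidate source. Their score lies near the floor (-1.72 ± 1.11 in control, Ccl5 and Lck at 6.51 ± 5.13 and 0.967 ± 0.590 CPM). Within genotypes both scores gave r = 0.873 (rho = 0.889, both permutation p = 1.00e-05, adjusted 4.00e-05, n = 26). 100000 permutations give no smaller p. Without Notch1-/- replicate 2 and control replicate 1, r was 0.839. The lists share 0 of 10 genes. The interferon gamma scores left a gap from 4.16 to 5.26, with 11 libraries above it and 15 below, where r was 0.896 (permutation p = 1.30e-04) and 0.0296 (p = 0.923), a split by the score itself that narrows its range, so how far r rests on the gap stays open. RNA of microglia and macrophages in the sort cannot be told apart (r = 0.462, rho = 0.407, permutation p = 0.0475 and 0.0778, adjusted 0.0951 and 0.156; r = 0.453 without Notch1-/-Notch2-/- replicate 3 and control replicate 4). A response of the tumour cells themselves stays open.

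Genes that changed in Notch2-/- lay near Notch2: 10 of 379 within 20 Mb passed against 36 of 15238 other genes, Notch2 counted with these (odds ratio 11.4, two-sided Fisher's exact p = 1.18e-07, adjusted p = 8.24e-07 over 7 tests), with 5 without Notch2-/- replicate 1 or 5 and odds ratios of 6.27 to 18.1 without 1 library at a time. Fisher's test ignores that neighbours such as the S100a genes may move together. Flanking DNA of another strain that came with the Notch2 allele may be the cause, a hypothesis: at all 10 of these genes the difference of Notch1-/-Notch2-/- from Notch1-/- had the same sign, though it was only 0.0487 for Wars2, -0.0597 for S100a13 and -0.18 for S100a6, less than the standard error of their change in Notch2-/-, and 10 passed as in Notch2-/- in Notch1-/-Notch2-/- against control, 4 in Notch1-/-, where 5830417I10Rik passed the other way (0.55, adjusted p = 0.00888), and 2 in Rbpj-/-. Flanking DNA around Notch1 cannot be told apart for the genes that changed in Notch1-/-, since 26.8% of genes elsewhere passed and a small excess would not show (odds ratio 0.860, Fisher's exact p = 0.293, adjusted p = 0.341), while around Rbpj the odds ratio in Rbpj-/- was 1.53 (adjusted Fisher's exact p = 0.0637). An effect of losing Notch2 on its neighbours stays open, and chromosome 17, far from any of the deleted genes, was also rich in passing genes, at an odds ratio of 7.58 (adjusted Fisher's exact p = 4.93e-06; 4.60 without control replicate 4).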

How the results depend on the processing

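The alternatives without the libraries that held both Xist and Ddx3y, with both cell scores as covariates and without genes near the deleted loci, the lists without each library, the overlap of Notch1-/- with Notch1-/-Notch2-/-, the overlap of both single losses in genes with a mean log2 CPM of at least 3, and the overlaps without each library were chosen only after the result was seen.

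Changed genes numbered 2378 for Rbpj-/-, 5794 for Notch1-/-Notch2-/-, 4174 for Notch1-/-, 46 for Notch2-/-, 124 for Rbpj-/- against Notch1-/-Notch2-/-, 482 for Notch1-/- against Notch2-/- and 12 for the interaction, against control where no other group is named. Counts that moved by more than 1.5 times were 1533 for Rbpj-/-, 16 for Notch2-/-, 73 for Rbpj-/- against Notch1-/-Notch2-/- and 193 for Notch1-/- against Notch2-/- with a stricter filter. With DESeq2 there were 343 for Notch2-/-, 313 for Rbpj-/- against Notch1-/-Notch2-/-, 1097 for Notch1-/- against Notch2-/- and 139 for the interaction. With voom there were 3747 for Rbpj-/-, 6907 for Notch1-/-, 1790 for Notch2-/-, 1904 for Notch1-/- against Notch2-/- and 924 for the interaction. With only the compared libraries in the fit there were 1222 for Rbpj-/-, 182 for Notch2-/-, 31 for Rbpj-/- against Notch1-/-Notch2-/- and 294 for Notch1-/- against Notch2-/-. With the microglia and macrophage score there were 42 for Rbpj-/-, 579 for Notch1-/-Notch2-/-, 15 for Notch1-/-, 17 for Notch2-/- and 7 for the interaction. With the endothelial score as well there were 4 for Rbpj-/-, 39 for Notch1-/-Notch2-/-, 3 for Notch1-/-, 24 for Notch2-/- and 8 for Notch1-/- against Notch2-/-. With Xist as a covariate there were 301 for Notch1-/- against Notch2-/- and 7 for the interaction. Without the libraries that held both Xist and Ddx3y there were 1492 for Rbpj-/-, 12 for Notch2-/-, 76 for Rbpj-/- against Notch1-/-Notch2-/-, 142 for Notch1-/- against Notch2-/- and 5 for the interaction. With no filter there were 81 for Rbpj-/- against Notch1-/-Notch2-/-. Size factors of DESeq2 and the removal of genes near the deleted loci moved no count by that much. A stricter filter tests fewer genes. The microglia and macrophage score differs mostly between genotypes, so it cannot separate genotype from leukocyte RNA. For the other settings the cause was not tested.

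Without 1 library at a time, the counts ranged from 1132 to 3292 for Rbpj-/-, 4639 to 6256 for Notch1-/-Notch2-/-, 2815 to 5290 for Notch1-/-, 21 to 83 for Notch2-/-, 21 to 156 for Rbpj-/- against Notch1-/-Notch2-/-, 275 to 841 for Notch1-/- against Notch2-/- and 5 to 227 for the interaction. The numbers of called lists ranged from 12 to 17 for Rbpj-/-, 10 to 15 for Notch1-/-Notch2-/-, 9 to 16 for Notch1-/-, 12 to 17 for Notch2-/-, 2 to 5 for Rbpj-/- against Notch1-/-Notch2-/- and 12 to 19 for Notch1-/- against Notch2-/-, where Rbpj-/- against Notch1-/-Notch2-/- had 3 with all libraries and 5 without Rbpj-/- replicate 1 or 2. The correlations of effects ranged from 0.714 to 0.843 for Rbpj-/- and Notch1-/-Notch2-/-, 0.409 to 0.610 for Notch1-/- and Notch2-/- and 0.809 to 0.860 for Notch1-/- and Notch1-/-Notch2-/-, and that of Notch1-/- and Notch1-/-Notch2-/- was 0.737 as a mean over split controls. The cause of these shifts was not tested.

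Called lists numbered 14 for Rbpj-/-, 14 for Notch1-/-Notch2-/-, 12 for Notch1-/-, 15 for Notch2-/-, 3 for Rbpj-/- against Notch1-/-Notch2-/- and 15 for Notch1-/- against Notch2-/-. With an estimated correlation there were 1 for Rbpj-/-, 0 for Notch1-/-Notch2-/-, 1 for Notch1-/-, 0 for Notch2-/-, 0 for Rbpj-/- against Notch1-/-Notch2-/- and 2 for Notch1-/- against Notch2-/-; with fry, 6 for Rbpj-/-, 0 for Notch2-/-, 1 for Rbpj-/- against Notch1-/-Notch2-/- and 8 for Notch1-/- against Notch2-/-; and with the microglia and macrophage score, 7 for Rbpj-/-. An estimated correlation widens the variance allowed for a list.

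Under the microglia and macrophage score as a covariate, camera's direction turned for these lists, given with their mean log2 fold change. In Rbpj-/- they were 0.0714 for microglia and macrophage, 1.12 for infiltrating myeloid, 2.0 for T and NK cell, 1.06 for MHC class I, 1.64 for MHC class II, 1.28 for interferon gamma and 0.72 for type I interferon. In Notch1-/-Notch2-/- they were 0.0642 for microglia and macrophage, 3.21 for T and NK cell, 1.77 for MHC class I, 2.87 for MHC class II, 2.17 for interferon gamma and 1.94 for type I interferon. In Notch1-/- they were 0.10 for microglia and macrophage, 1.38 for infiltrating myeloid, 4.04 for T and NK cell, 2.63 for MHC class I, 4.80 for MHC class II, 4.12 for interferon gamma, 2.41 for type I interferon, -0.33 for cell cycle and -0.22 for MAPK output. The microglia and macrophage list also turned, to 0.0282 in Notch2-/-, 0.00719 in Rbpj-/- against Notch1-/-Notch2-/- and 0.0725 in Notch1-/- against Notch2-/-, which the covariate brings about by construction, being that list's own mean. Camera's adjusted p in the new direction was below 0.05 for T and NK cells in these 3 genotypes, for MHC class I and both interferon lists in Notch1-/-Notch2-/- and Notch1-/-, and for MHC class II, cell cycle and MAPK output in Notch1-/-. For the other lists the cause was not tested.

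The 655 values of genes that the naming rule gives were repeated 14921 times over these settings, and 13081 repeats kept direction and side of the threshold, 1693 lost the call, 78 gained one and 69 reversed. Of those that passed, the call held without each single library for 42 of 84 in Rbpj-/-, 104 of 116 in Notch1-/-Notch2-/-, 74 of 98 in Notch1-/-, 8 of 21 in Notch2-/-, 6 of 26 in Rbpj-/- against Notch1-/-Notch2-/-, 26 of 49 in Notch1-/- against Notch2-/- and 4 of 8 in the interaction. The genes described in the report were picked from these after the values were seen, with preference for calls that held, so these counts and not the genes described show how firm the calls were.

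Log2 fold changes that turned with the microglia and macrophage score as a covariate were these. In Rbpj-/-, they were Ccl3 (0.11), Cd22 (0.71), Csf1r (0.0234) and Zfp36 (0.26). In Notch1-/-Notch2-/-, they were Ccl3 (0.52), Ccl4 (0.26), Ccl5 (0.62), Cd22 (1.25), H2-DMa (1.17), H2-Ob (0.48), Irf2 (0.0367), Ly6c2 (0.34) and Lyz2 (1.34). In Notch1-/-, they were Atf3 (0.31), Ccl5 (0.89), Ccnd1 (-0.14), Cd22 (0.93), Cxcl11 (2.05), H2-Oa (0.91), H2-Ob (1.98), Jag1 (-0.18), Ly6a (0.0922), Ms4a4c (2.66), Nefm (-0.00944), Ntng1 (-0.41) and Vgf (-1.21).

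Log2 fold changes that turned with both scores as covariates were these. In Rbpj-/-, they were Ccl3 (0.54), Ccl4 (0.0498), Cd22 (0.30), Cd79b (0.22), Csf1r (0.000194), Dll4 (0.0809), Ly6c2 (0.36), Pecam1 (0.42) and Zfp36 (0.41). In Notch1-/-Notch2-/-, they were Ccl2 (0.97), Ccl3 (1.17), Ccl4 (0.74), Cd22 (0.64), Cd79b (0.52), H2-DMa (0.47), Ly6c2 (1.83) and Lyz2 (2.07). In Notch1-/-, they were Atf3 (0.19), Ccl12 (0.0172), Ccl2 (0.68), Ccl3 (0.24), Ccnd1 (-0.26), Cd22 (0.0829), Cd79b (0.78), Cxcl11 (2.48), Dll4 (0.0525), Elavl4 (-0.12), Esam (0.0678), H2-Ob (0.21), Ly6a (0.20), Ly6c1 (0.32), Ly6c2 (1.52), Lyz2 (0.70), Ms4a4c (2.46), Nefm (-0.52), Notum (0.27), Ntng1 (-0.29), Spred3 (-0.0614), Tyrobp (0.0726), Vgf (-1.58) and Zfp36 (0.25). In Notch1-/- against Notch2-/-, they were Ccl3 (0.40) and Ly6c1 (0.28). The cause was not tested.

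Pairing by replicate number stays open. Deviations of same-numbered libraries from group means correlated at over 0.1 in 0 of 4, 2 of 5, 2 of 6, 2 of 5, 2 of 4 and 0 of 5 pairs for the groups compared (-0.342 to 0.627). With the number as a block, 1304 genes changed for Rbpj-/-, 5245 for Notch1-/-Notch2-/-, 3884 for Notch1-/-, 25 for Notch2-/-, 50 for Rbpj-/- against Notch1-/-Notch2-/-, 300 for Notch1-/- against Notch2-/- and 6 for the interaction, and 6 lists were called for Rbpj-/- against Notch1-/-Notch2-/-.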

Other observations

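Which chromosomes held the 46 genes that changed in Notch2-/- was asked after the result was seen. Chromosome 17 held 13 of them among 782 genes tested (odds ratio 7.58, two-sided Fisher's exact p = 2.47e-07, adjusted p = 4.93e-06), and chromosome 3, where Notch2 lies, held 12 of 756 (odds ratio 7.03, p = 1.29e-06, adjusted p = 1.29e-05 by the same test over 20 chromosomes). Those on chromosome 17, chosen after their values were seen, include the chemokine receptor Ccr6 (-3.10 ± 0.68, adjusted p = 0.0412), the secretory protein gene Crisp1 (-6.49 ± 1.26, adjusted p = 0.0212) and the class I-like MHC gene H2-T3 (-4.67 ± 0.92, adjusted p = 0.0200), which fell, and the DNA polymerase Polh (0.71 ± 0.14, adjusted p = 0.0171), which rose, as edgeR tested them. In Notch1-/-Notch2-/- against control the same genes stood at -5.29, -6.27, -1.91 and 0.50, with edgeR's adjusted p of 7.05e-05, 7.67e-04, 0.0432 and 0.00634. D330041H03Rik (-1.44), Rnf151 (-4.29) and Rps2 (5.05), also on chromosome 17, did not pass there, at 0.23, -0.11 and 0.80 (edgeR's adjusted p = 0.513, 0.891 and 0.399). Without 1 library at a time chromosome 17 held 6 to 17 passing genes, with 6 without Notch2-/- replicates 1, 4 or 5 or control replicate 2, and odds ratios of 4.60 to 10.6. Fisher's test ignores that genes such as Rnaset2a and Rnaset2b may move together.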
